A study of Homo sapiens with 2 samples.

How the data were processed

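Gene expression was measured in 2 samples of the Hep3B line, 1 with a caveolin-1 hairpin and 1 with a non-target hairpin, each on 1 Affymetrix HG-U133 Plus 2.0 array, per the file headers and the labels. Total RNA was extracted with Trizol and labelled with biotin, per the labels' protocols. The samples were grouped by their titles. The processing tool named is RMA, per the submitters' processing notes, which corrects background, quantile-normalizes probes and summarises each probe set by median polish. Its version, the annotation release and the genome build are not given in the sources used here. Quantile normalization assumes equal distributions of signal, so a difference in total RNA output between the lines would not be seen.

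The deposited series values are log2 values that the authors centred per probe set on the mean of both samples. Both columns mirror each other, with a largest row sum of 1e-06 and a median of 0 in each column, so they hold differences and no levels. The scale and direction were settled from the authors' deposited table of differences, whose log2 values equal the shCav1 minus shCtl difference for all 244 listed probe sets within 1e-05. That table also gives a linear fold (larger over smaller) by the authors for each listed probe set. A further deposited table holds a linear signal intensity per probe set, per the file headers. Its control column was mapped to shCtl by name. The other column, 1 in number, has a name that matches no label and was not used. Levels in shCav1 were therefore computed as the shCtl signal multiplied by the fold from the series values, which takes both to be on 1 scale. No detection call is used here.

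Gene symbols came from the authors' deposited tables of higher and lower probe sets. Of the 244 entries 218 carry 1 symbol, 3 several and 23 none. Entrez identifiers matched 217 entries to RefSeq genes of GRCh38.p14, which updated 15 symbols for the matching of gene lists, while the text keeps the deposited symbols. The other probe sets of the array have no gene name here. Of 214 deposited alignments 40 overlapped their gene's place in GRCh38.p14, so coordinates are given as deposited and were not combined with that assembly.

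The log2 difference is shCav1 minus shCtl. The 62 control probe sets were left out. A probe set was kept when the higher of both arrays was at or above the median of all values, a linear signal of 30.7, which kept 28128 of 54613 probe sets (51.5%). A probe set was counted at a difference of at least 2-fold. A gene's representative was its listed, kept probe set with the highest mean signal. Because 1 array per group leaves no residual degrees of freedom, no test was run. SDs are given between probe sets of 1 gene and are technical.

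The following were fixed before the data were examined: the comparison, the filter, the limit, the alternatives, 39 gene lists and the rule for named genes. That rule takes CAV1, the 12 kept genes with the largest increase and the 12 with the largest decrease (1 symbol, passing over uncharacterised names), and up to 4 kept members per list. Of the 39 lists 1, with an item that is not reported here, was left out, and 31 genes given by the rule are reported. MAGEA2 and MAGEA2B in the report, and the further genes of the closing section, were chosen after their values were seen. The plan assumed gene names for all probe sets. Without them, counts are of probe sets instead of genes, list medians with 10000 random lists could not be computed, and probe set agreement covers listed probe sets.

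Alternatives were no brightness filter, a filter at the 75th percentile, centring on the median, a loess curve on mean log2 value (span 0.3), quantile normalization of the levels, a pseudocount of 16 on the linear scale, and limits of 1.5-fold and 3-fold. Centring on 18 probe sets of hybridization spikes, a filter at the 75th percentile of the mean of both arrays and leaving out probe sets with _s_at or _x_at names were added after seeing the data. The counting was tested on simulated data for this comparison, with 200 probe sets changed by known folds among 54613. Differences of the unchanged probe sets were drawn from a normal distribution with the robust SD found at their brightness. The counting recovered 2.0% of those changed 1.5-fold, 96.0% at 2.5-fold, 100.0% at 3-fold and 98.0% at 4-fold. No unchanged probe set passed 2-fold, which follows from the narrow normal spread. The wider tails of the observed differences were not simulated, so this gives no rate of false calls. Pairs of listed genes at most 5 protein-coding genes apart were found in the gene order of GRCh38.p14. Their number, and the annotation terms held by at least 10 listed genes, were set against 10000 random reassignments of direction over the listed genes, for the terms over those reported here. The pairs were counted again after centring on the spikes and among genes past the brightness filter, also after seeing the data. Gene Ontology process cells that read as removed in 16 entries were not used. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.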

Results

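Total RNA was profiled on 1 array from Hep3B cells carrying a short hairpin against caveolin-1 (shCav1) and on 1 array from Hep3B cells carrying a non-target control hairpin (shCtl). Hep3B is an established human hepatocellular carcinoma line, and caveolin-1, encoded by CAV1, is the main coat protein of caveolae, the small flask-shaped pits of the plasma membrane. The array was the Affymetrix HG-U133 Plus 2.0, whose 54675 probe sets include 62 for controls, which left 54613. The median signal of these on the shCtl array was 30.6 on the linear scale, with values from 4.40 to 25292. With 1 array per group no difference has a replicate check, no test between the groups is possible and no p-value is given. The number of arrays therefore limits the precision of every value, and genes were ranked by a fixed rule of size, a difference of at least 2-fold. The single comparison in the design asks which transcripts differ in level between the shCav1 and the shCtl sample. With 1 sample of each, an effect of lower CAV1 cannot be told apart from other effects of the hairpin. Nor can it be told apart from other differences between the 2 samples.

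CAV1, the target of the hairpin, was the gene with the largest decrease in the shCav1 sample. Its signal was 6.61% of that in shCtl at probe set 212097_at, where the linear signal was 935 in shCtl and 61.8 in shCav1. At the other listed CAV1 probe set, 203065_s_at, it was 7.38%, from 524 to 38.7. The log2 difference over both was -3.84 ± 0.11 (SD over 2 probe sets of the same array pair, which is technical and not biological spread). The authors' deposited table gives a fold decrease of 15.1 and 13.5 for these probe sets. Both align to the plus strand of chromosome 7, at positions 116199521 to 116201233 and 116165091 to 116199607 in the deposited alignments, whose genome build is not given in the sources used here. The direction matched the label of each sample. Of the 13 genes in the preset caveola list, which holds CAV2, the cavins, EHD2 and the flotillins among others, CAV1 was the member listed past 2-fold.

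Beyond CAV1, 141 of the 28128 probe sets bright enough to be kept were at least 2-fold higher in shCav1 and 84, the CAV1 probe sets included, were at least 2-fold lower. Probe sets with 1 gene symbol among them named 114 genes that were higher and 62 that were lower. The spread of differences over all kept probe sets was narrow, with a robust SD of 0.21 on the log2 scale, and 96.0% of them differed by less than 1.5-fold. The higher share of the 2-fold probe sets was 62.7%, but this split depended on how the arrays were set against each other. The 18 probe sets for bacterial hybridization spikes were all higher on the shCav1 array, by a median log2 difference of 0.14 (range 0.07 to 0.25). They cover only the bioB, bioC, bioD and cre transcripts, so they are not 18 independent values. Their shCtl signals ran from 498 to 18840, far above the array median. When differences were centred on these spikes, a setting chosen after seeing the data, 102 probe sets were higher and 142 lower, so that the higher share was 41.8%. Without this centring the share was 48.8% at a 1.5-fold limit, with 552 higher and 578 lower. At a 3-fold limit it was 72.4%, with 42 higher and 16 lower.

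**Figure D1:**
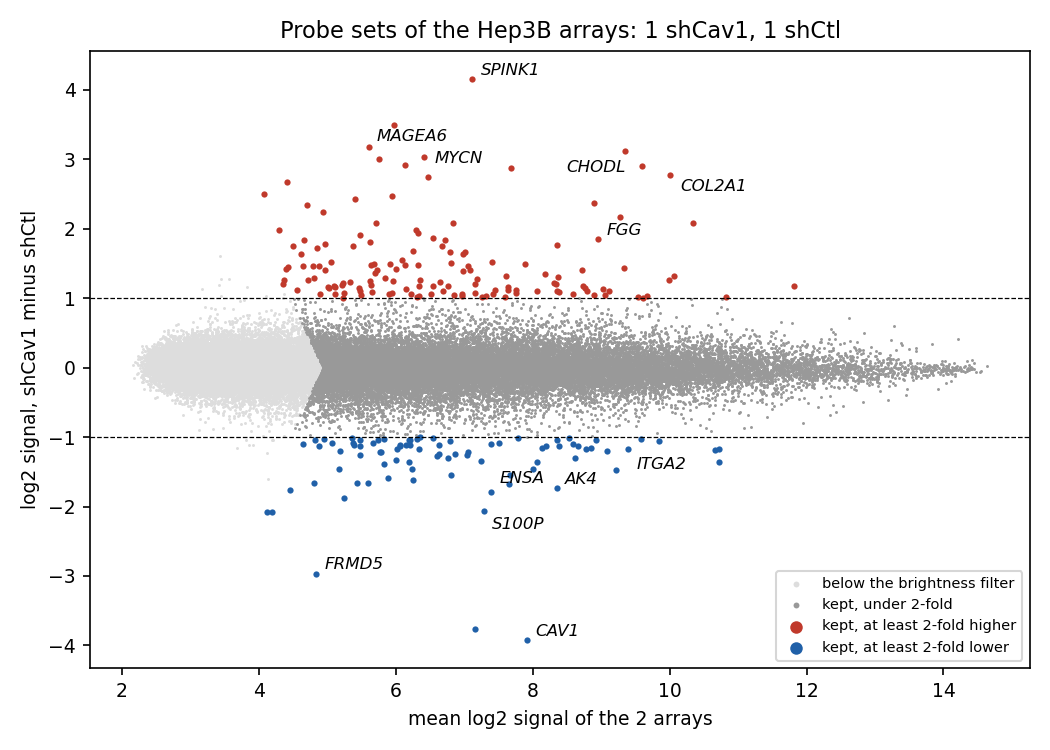
Difference between the arrays in log2 signal, shCav1 minus shCtl (vertical axis), against the mean log2 signal of both arrays (horizontal axis), 1 point per probe set; dashed lines mark 2-fold. Kept probe sets at least 2-fold higher (141) are red and those at least 2-fold lower (84) blue, with CAV1 at the bottom and SPINK1 at the top.

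SPINK1, which encodes a secreted trypsin inhibitor, was the gene with the largest increase. Its signal was 32.9 in shCtl, close to the array median, and 587 in shCav1, a log2 difference of 4.16, and the authors' deposited table gives 17.9-fold. Under a pseudocount of 16 the SPINK1 log2 difference was 3.63. MYCN, a transcription factor of the MYC family, was 8.20-fold higher, from 29.7 to 243. Members of the MAGE-A family of cancer-testis antigens were also among the genes with the largest increases. MAGEA6 was 9.03-fold higher and MAGEA3 7.56-fold higher. A pair of probe sets assigned jointly to MAGEA2 and MAGEA2B was 11.3-fold and 6.35-fold higher, from shCtl signals of 18.7 and 8.43 below the array median; under a pseudocount of 16 the log2 differences were 2.71 instead of 3.498 and 1.51 instead of 2.67. The MAGE-A genes on Xq28 are near-identical in sequence, so probes can bind transcripts of more than 1 of them, and their separate values are uncertain. VSIG1, an immunoglobulin-domain membrane protein, was 8.02-fold higher, and the lectin gene CHODL was 7.52-fold higher, from 281 to 2114.

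COL2A1, the gene of the main fibrillar collagen of cartilage, was higher at both of its listed probe sets, with a log2 difference of 2.82 ± 0.06 (SD over 2 probe sets). The signal of its brighter probe set was 391 in shCtl and 2682 in shCav1. MUM1L1 was 6.70-fold higher, CRISPLD1 5.66-fold, CCDC141 5.40-fold and BCHE, which encodes butyrylcholinesterase, 5.05-fold. The shCtl signal of MUM1L1 was 34.4, close to the array median, and under a pseudocount of 16 its log2 difference was 2.29 instead of 2.74. For the zinc finger gene ZNF22 the listed probe sets differed from each other more than for any other gene, with log2 differences of 2.46 and 1.46. Several of these genes were dim in shCtl: the shCtl signal was 7.09 for CRISPLD1, 11.6 for BCHE, 16.2 for MAGEA6, 18.2 for CCDC141, 19.0 for VSIG1, 25.5 for MAGEA3, 26.1 for ZNF22 and 29.7 for MYCN, all below the array median. At such levels background takes a large part of the signal, and the fold is less certain than for COL2A1 or CHODL. Under a pseudocount of 16 the log2 difference was 1.28 instead of 2.501 for CRISPLD1, 1.43 instead of 2.34 for BCHE, 2.33 instead of 3.17 for MAGEA6, 1.74 instead of 2.43 for CCDC141, 2.27 instead of 3.004 for VSIG1, 2.33 instead of 2.92 for MAGEA3, 1.93 instead of 2.46 for ZNF22 and 2.51 instead of 3.04 for MYCN.

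Among the genes with lower signal, FRMD5, a gene of the FERM-domain family, followed CAV1 with 12.8% of its shCtl signal, from 79.9 to 10.2. XK, which encodes a membrane protein of red blood cells, was at 23.6%. CDC42EP3, an effector of the small GTPase CDC42, was at 23.7%, and the calcium-binding protein gene S100P at 24.0%, from 319 to 76.5. ENSA, which encodes an inhibitor of protein phosphatase 2A, was at 29.0%. AK4, a mitochondrial adenylate kinase, was lower at 3 probe sets, with a log2 difference of -1.48 ± 0.23 (SD over 3 probe sets). TSPO, a protein of the outer mitochondrial membrane, was at 31.4%. The protease inhibitor CSTA was at 31.6% and PRTFDC1 also at 31.6%. The transcription factor KLF4 was at 33.2%, and CA2, a carbonic anhydrase, was at 34.3%. Some of these genes were dim in shCav1, with a signal of 10.2 for FRMD5, 8.40 for XK, 8.87 for CDC42EP3, 15.7 for PRTFDC1 and 24.2 for CSTA, so that their percentages are less certain. Under a pseudocount of 16 the log2 difference was -1.87 instead of -2.97 for FRMD5, -1.08 instead of -2.08 for XK, -1.10 instead of -2.07 for CDC42EP3, -1.05 instead of -1.66 for PRTFDC1 and -1.21 instead of -1.66 for CSTA. For KLF4 it was -1.24 instead of -1.59.

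**Figure D2:**
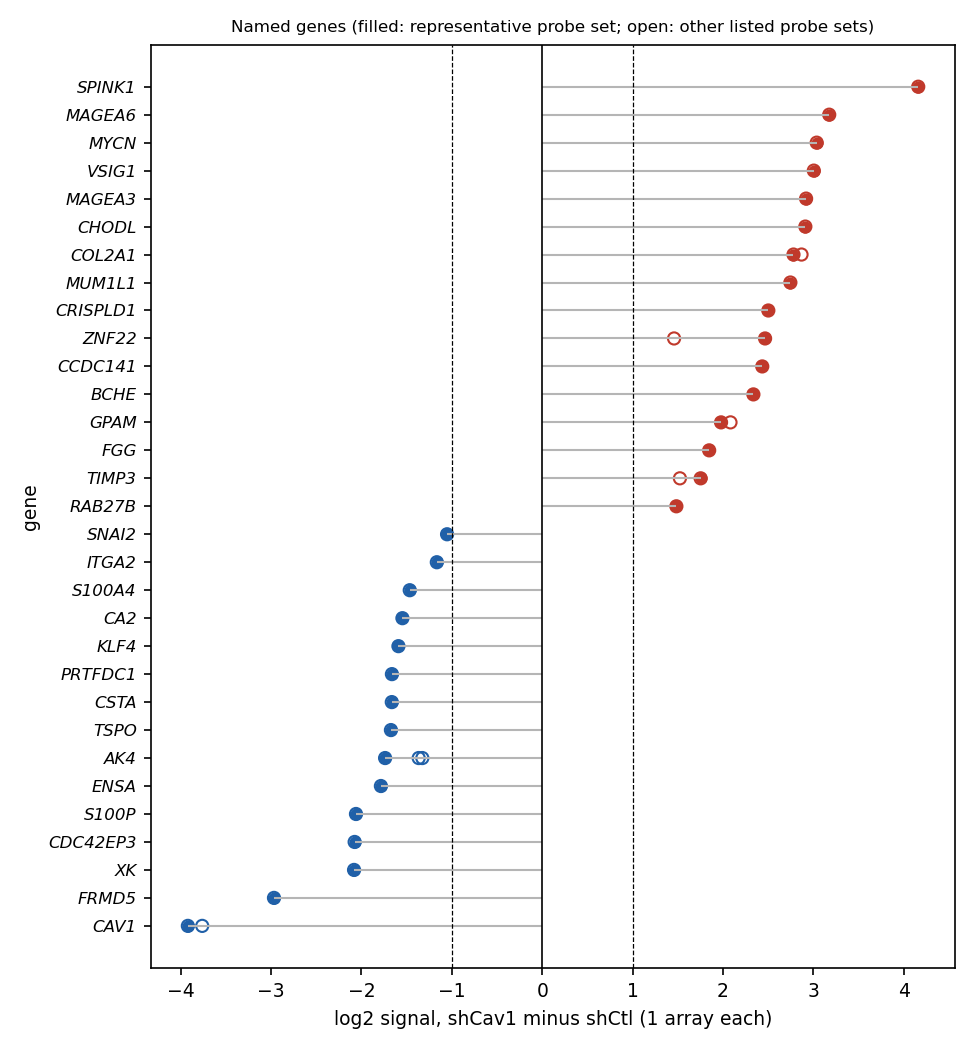
Log2 signal in shCav1 minus shCtl (horizontal axis) for the 31 named genes (vertical axis), 1 array per group. Filled points are the representative probe set and open points other listed probe sets of the gene; dashed lines mark 2-fold, and values run from -3.92 for CAV1 to 4.16 for SPINK1.

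Of 38 gene lists fixed before the data were examined, with 568 different members, 8 held a member listed past 2-fold, and 9 members were listed in all, 4 higher and 5 lower. These counts carry no test, because the probe sets under 2-fold have no gene names in the tables used here, so that a list's median could not be computed. In the list of mesenchymal transition genes 2 of 16 members were lower. They were S100A4, a calcium-binding protein, at 36.2% of its shCtl signal, and SNAI2, a transcriptional repressor, at 48.2%. In the list of integrin and focal adhesion genes, ITGA2, the alpha-2 integrin subunit, was at 44.6%, from 1007 to 449. KLF4, given above, was the listed member among 18 immediate early genes.

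The other listed members were higher in shCav1. Among 20 secreted hepatocyte proteins it was FGG, the fibrinogen gamma chain, at 3.60-fold, from 263 to 944. Among 15 genes of fatty acid and triglyceride synthesis it was GPAM, a glycerol-3-phosphate acyltransferase of mitochondria, with a log2 difference of 2.03 ± 0.07 (SD over 2 probe sets). TIMP3, an inhibitor of matrix metalloproteinases, had a log2 difference of 1.64 ± 0.16 (SD over 2 probe sets) among 17 matrix proteases and inhibitors. RAB27B, a GTPase of vesicle secretion, was 2.80-fold higher among 17 genes of vesicle trafficking. TIMP3 and RAB27B were below the array median in shCtl, with signals of 22.5 and 29.7 at their representative probe sets. Under a pseudocount of 16 the log2 difference of SNAI2 was -0.92, under 2-fold, that of TIMP3 1.25 instead of 1.75 and that of RAB27B 1.12 instead of 1.484. That of GPAM was 1.63 instead of 1.98 at its representative probe set.

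No member was listed past 2-fold in the remaining 30 lists. These were the lists of liver transcription factors, bile acid and xenobiotic metabolism, fatty acid oxidation, glycolysis, hypoxia response, replication, mitosis, p53 targets, epithelial junctions, extracellular matrix, YAP and TEAD targets, Wnt targets, TGF-beta response, NF-kB and chemokines, interferon response, unfolded protein response, heat shock, NRF2 targets, metallothioneins, growth factor receptors and ligands, apoptosis regulators, caveola signalling partners, the mitochondrial respiratory chain, ribosomal proteins and reference genes. The same held for the 5 lists of other cell types, with 55 entries in all, which covered hepatic stellate cells and fibroblasts, endothelium, macrophages, lymphocytes, and cholangiocytes and progenitors. Differences under 2-fold in these lists are not excluded.

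The 2-fold probe sets were set beside the authors' deposited tables, which list 152 probe sets as higher and 92 as lower. All 244 listed probe sets had the direction and the log2 difference of the series values, within a tolerance of 1e-05, and no probe set past 2-fold was outside the tables. The tables thus hold the 2-fold cut of these same values, so the match is no separate support for any difference. After the brightness filter 225 of them remained. Of the 190 genes named by a single symbol, 23 had at least 2 listed probe sets, 15 of them higher and 8 lower, and no gene was in both tables. The median SD between the listed probe sets of 1 gene was 0.16 on the log2 scale. A gene's further probe sets that did not reach 2-fold are unnamed here, so this agreement is partly set by the selection.

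Control probe sets differed between the arrays by end of transcript. The 5' probe set was lower relative to the 3' probe set on the shCav1 array in 12 of 14 pairs of control probe sets. These pairs include each bacterial polyadenylated spike more than once. For AFFX-HSAC07/X00351 the log2 differences were -0.88 at the 5' end and -0.22 at the 3' end. For AFFX-HUMGAPDH/M33197 they were -0.24 and -0.05, and for AFFX-HUMISGF3A/M97935 0.05 and 0.39, where the 5' probe set was dim, with a shCtl signal of 22.8. The same order held in all 8 pairs for the bacterial polyadenylated spikes, with a median 5' minus 3' difference of -0.19 (range -0.70 to -0.05). These pairs cover only the dap, lys, phe and thr transcripts, each under more than 1 name, such as AFFX-DapX and AFFX-r2-Bs-dap. They are therefore not 8 independent values. Of the 3 other controls with both ends, AFFX-M27830 had log2 differences of -0.41 at the 5' end and -0.11 at the 3' end, while the order was opposite for AFFX-HUMRGE/M10098, with 0.03 and -0.03, and for AFFX-TrpnX, with 0.28 and 0.05, at a shCtl signal of 10.1 and 6.69 near the floor. None of the 62 control probe sets reached 2-fold.

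**Figure D3:**
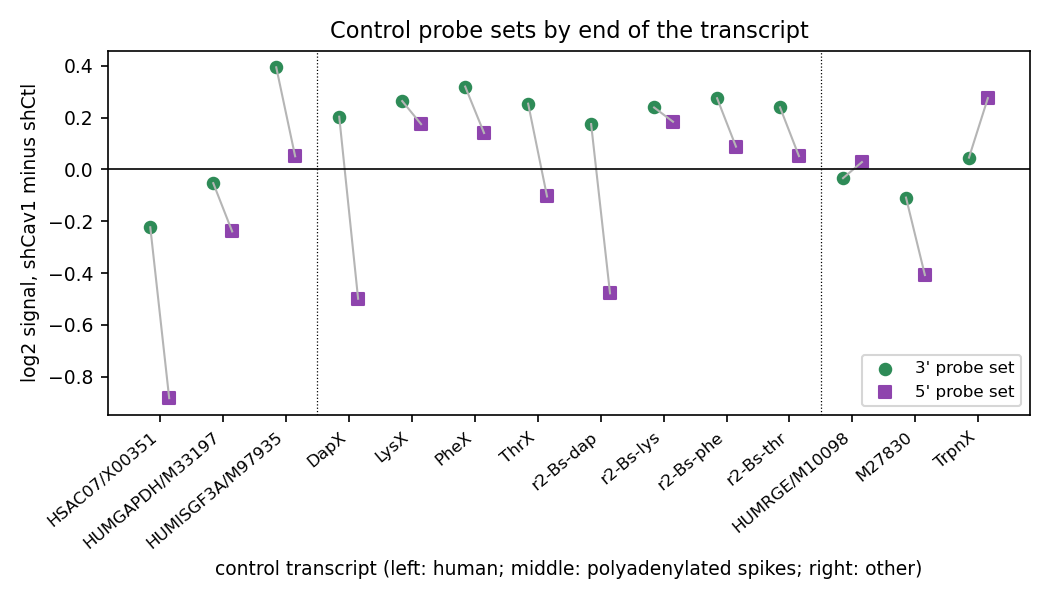
Log2 signal in shCav1 minus shCtl (vertical axis) for the 3' and 5' probe sets of 3 human control transcripts (left), 8 pairs of polyadenylated spikes (middle) and 3 other controls (right; horizontal axis). A line joins the ends of each transcript, and the 5' value lies below the 3' value in 12 of 14 pairs.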

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

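The counts of 141 higher and 84 lower probe sets stayed within 1.5 times under no filter, median centring, loess, quantile normalization and without _s_at and _x_at probe sets. Median centring, loess and quantile normalization had little room to move the counts, because RMA had already quantile-normalized the values. The median log2 difference among kept probe sets was -0.0067. A filter at the 75th percentile, which tests fewer probe sets, gave 79 higher and 43 lower, together 122 of the listed entries (225 in the main setting). It gave 10 genes with agreeing probe sets (20 in the main setting). A filter at the 75th percentile of the mean of both arrays, chosen after seeing the data, gave 51 higher and 34 lower. A pseudocount of 16, which shrinks dim differences, gave 91 higher and 49 lower, together 140 listed entries. It gave 12 genes with agreeing probe sets and a CAV1 log2 difference of -3.61 against -3.92. A limit of 1.5-fold gave 552 higher and 578 lower, and 3-fold gave 42 and 16. Centring on the hybridization spikes, chosen after seeing the data, gave 102 higher, 142 lower, a CAV1 log2 difference of -4.05 and 8 neighbouring pairs of different families both higher instead of 13. With genes past the brightness filter, also chosen after seeing the data, there were 12 such pairs. Under the pseudocount most of the 13 pairs had a gene under 2-fold. The pseudocount moved 19 of the 30 named genes other than CAV1 by more than the robust SD of 0.21. Means over all probe sets of a gene, the deposited linear table as source, and list medians with random lists, matched or unmatched, were not run. The reason was a lack of gene names or of a column that a label matches. For CAV1 the mean over its listed probe sets was -3.84. No paired analysis was possible because each group has 1 sample. Signal over background limits the dim genes: 58 of the 152 higher probe sets and 8 of the 92 lower ones lay below the array median in shCtl, and 11 and 28 did in shCav1. These counts follow in part from the selection, since every listed probe set is lower on 1 of the arrays.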

Other observations

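The genes and tests in this part were chosen after the values were seen. Exceptions are the filter on the brighter array at the 75th percentile and the limits of 1.5-fold and 3-fold. The random reassignment of neighbouring pairs was not in the plan fixed before the data were examined. Only its prediction was written before its result. Listed genes annotated to the extracellular region in the deposited tables were mostly higher in shCav1, 27 genes higher against 3 lower. Of these genes 3 of the higher ones and 0 of the lower ones had no probe set past the brightness filter, which leaves 24 against 3. Of 33 annotation terms compared, 1 or more came out as uneven in 3.22% of 10000 random reassignments of direction, which describes these arrays and is no test of the knockdown. The higher genes of this term included CFB with a log2 difference of 1.52, SERPING1 with 1.49, C1S with 1.25, MBL2 with 1.08 C4BPA with 1.02 and A2M with 1.32, beside FGG given above. They also included the collagen genes COL4A5 with 1.99 and COL5A2 with 1.22 ± 0.06 (SD over 2 probe sets), and LIPG, a lipase of endothelium, with 1.72. COL4A5, LIPG and MBL2 were below the array median in shCtl, with signals of 9.88, 15.9 and 26.0, and under a pseudocount of 16 their log2 differences were 1.09, 1.10 and 0.76. C1S, at a shCtl signal of 32.0, fell to 0.94 under the pseudocount, also under 2-fold. The 3 lower genes were TXLNA at -1.27, SERPINE2 at -1.18 and NPW at -1.13. Genes annotated to the cytoplasm went the other way, 22 higher and 27 lower, against an expected 31.4 higher, and 1 or more terms were as uneven in 2.7% of reassignments.

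Further genes had several probe sets past 2-fold, all in 1 direction. TM4SF1, a membrane protein of the tetraspanin-like family, was higher by 2.20 ± 0.15 on the log2 scale (SD over 3 probe sets), and THSD7A by 1.46 ± 0.16 (SD over 4). CD36, a fatty acid receptor, was higher by 1.27 ± 0.13 and NOTCH2 by 1.14 ± 0.0049 (SD over 2 each). CCND2, the cyclin D2 gene, was higher at both listed probe sets but by 2.08 and 1.26. TRPC4 was at 1.87 and GRIK2 at 1.78, each with a further listed probe set that failed the brightness filter and whose fold is not read here. Probe sets of these genes under 2-fold carry no gene name here, so the means and SDs cover the listed ones only. The dimmer probe sets of CD36, CCND2 and THSD7A, with shCtl signals of 22.8, 17.1 and 13.3, were below the array median, and under a pseudocount of 16 their log2 differences were 0.80, 0.78 and 0.71, under 2-fold. The kept GRIK2 probe set was also below the array median in shCtl, at 16.9, and its log2 difference under the pseudocount was 1.17 instead of 1.78. Among lower genes, APPL1, an endosomal adaptor, was at -1.21 ± 0.06 and the kinase anchor AKAP12 at -1.17 ± 0.13 (SD over 2 each), while CAPS ran from -1.62 to -1.09 over 3 probe sets. Under a pseudocount of 16 the listed AKAP12 probe sets fell under 2-fold, at -0.93 and -0.996. So did 1 probe set of APPL1, at -0.98, and the CAPS probe sets 231728_at, at -0.94, and 226424_at, at -0.996.

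More 2-fold probe sets were higher than lower, 141 against 84. Crowding of dim probe sets near the floor stays open. Above the 75th percentile of the brighter array 64.8% were higher, but that filter keeps probe sets whose dimmer array is near the floor. Above the 75th percentile of the mean of both arrays, a filter added, with its error margin, after that value was seen, 60.0% of the 51 higher and 34 lower probe sets were higher (binomial SE 5.3), and none had its dimmer array below the median. This is above an even split, but within its error of the bound set for excluding the floor. An offset between the arrays stays open: after centring on the hybridization spikes 41.8% were higher. The spikes had shCtl signals from 498 to 18840, against a median of 42.1 for the listed higher probe sets and 117 for the lower. The spikes thus do not measure the offset at those levels. Which reference is right, the array median or the spikes, cannot be decided from 1 array pair. The count of higher against lower probe sets at 2-fold may therefore be a matter of scaling. In the main scaling 72.4% were higher at a 3-fold limit, 42 against 16, and 48.8% at 1.5-fold. These limits were not counted again after centring on the spikes.

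Listed genes that lie close together on a chromosome were often both higher. Of 22 pairs at most 5 protein-coding genes apart, 15 were both higher, 1 both lower and 6 opposite. On the X chromosome MUM1L1, NRK and RNF128 were joined by such pairs, as were COL4A5 and VSIG1. All of these genes lie in band Xq22.3 in the deposited alignments. CCDC141 with TTN and BHLHE41 with SSPN were adjacent. CHORDC1 and FAT3, also adjacent in the gene order of GRCh38.p14, were opposite, as were SYTL5 with XK and SRPX with SYTL5 on the X chromosome. The first deposited alignment of the listed CHORDC1 probe set lies on chromosome 1, whereas the pair is on chromosome 11. For the FAT3 probe set no deposited position was read. Shared probes of near-identical paralogs are argued against as the whole cause, since 13 of the pairs were of different families, the other 2 being MAGE-A genes. The larger number of higher genes is argued against too: random reassignment gave at least 13 pairs of different families in 2.4% of 10000 draws, with a median of 8. This holds for the main scaling; centred on the hybridization spikes, a test chosen after the result was seen, 8 of the 13 pairs remained past 2-fold, and 0.2% of draws gave as many (median 3), though genes newly lower under that centring carry no name and are missing from it. Among genes with a probe set past the brightness filter, also chosen afterwards, 12 such pairs remained, and 1.8% of draws gave as many (median 7). Of the 13 pairs, only COL4A5 with VSIG1, IL1RAP with LEPREL1 and MUM1L1 with RNF128 stayed past 2-fold under a pseudocount of 16. Each of the other pairs had a gene under 2-fold, such as SIM1 at 0.65, NRK at 0.68, TTN at 0.79 and SPATA17 at 0.996 (log2). The reassignment was not repeated under the pseudocount. A copy number or clonal difference between the 2 cell lines could give such groups, and stays open because 0 probe sets outside the deposited lists carry a gene name, so the other genes of these stretches could not be examined; an effect of the knockdown on such stretches is untested.

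The 5' probe sets of control transcripts were lower relative to the 3' ones on the shCav1 array in 12 of 14 pairs, the exceptions being AFFX-HUMRGE/M10098 and AFFX-TrpnX. The probe sets of AFFX-TrpnX, and the 5' probe set of AFFX-HUMISGF3A/M97935 among the pairs with the common order, were below the array median in shCtl. The bacterial polyadenylated spikes, which do not come from the cells, showed the same order in all 8 pairs, with a median 5' minus 3' difference of -0.187 (SD 0.25 over pairs of few transcripts). Degraded RNA in the knockdown cells alone would leave the spikes near 0, and because their spread reaches close to 0 it cannot be told apart from a difference in the labelling reaction between the arrays, which may account for both. The effect on listed genes could not be examined without the positions of their probes within the transcripts.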
